A study of Mus musculus with 16 samples.

How the data were processed

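RNA was measured in pre-B cells grown from the bone marrow of wild type (wt) mice and of mice with a vav-Gfi1b transgene (tg), after infection with a retrovirus carrying the p210 form of the BCR-Abl oncogene. Each genotype was transformed with 2 constructs, MSCV-GFP-IRES-p210 (MSCV) and pSRa-p210-tkneo (pSRa), and each line received vehicle or 1E-08 M dexamethasone for 12 hours before RNA extraction. This gave 8 groups of 2 arrays, 16 arrays of the Affymetrix MOE430A type. Per the labels, cDNA was primed with oligo-dT and transcribed by T7 RNA polymerase with biotinylated nucleotides, and the arrays were scanned on a GeneChip scanner 2500.

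The deposited values are linear signal intensity, 1 value per probe set and array, without detection calls. Per the labels, the images were processed either by MAS 5.0 with global scaling to a target of 1000 or by RMAExpress. The values are those of MAS 5.0: their trimmed mean, with 2% left out at each end, was 1000.3 to 1000.4 in every array, and they run from 0.1 to 50830 on a linear scale. The median signal per array was 251 to 332, and 13.5 to 18.0% of probe sets lay below 32. On the arrays' own quality probe sets, the 3' to 5' log2 ratio was -0.49 to -0.28 for Gapdh and 0.15 to 0.43 for actin. No depth applies to arrays, and their number limits the precision.

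The deposited experiment records, which hold text and no other measurement, name the mouse, the experiment and the day of hybridization of each array. They give 8 mice, each the source of 1 vehicle and 1 dexamethasone array, and 1 chip lot. In experiment 1 the 4 vehicle arrays were hybridized on one day and the 4 dexamethasone arrays on another, so day and treatment cannot be separated there. In experiment 2 all 8 arrays were hybridized on a single day. The replicate number of a group is the number of the experiment. Pairing of the arrays by mouse was checked on the values: after the group means were removed, the residuals of a mouse's vehicle and dexamethasone arrays correlated across probe sets with r = 0.45 to 0.63 (genes are not independent replicates), against -0.06 to 0.22 between lines.

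Values were transformed as log2(value + 32). Of 22690 probe sets, 64 controls were left out and 22626 were tested. Of these, 20380 were listed with a single gene, 691 with several and 1555 with none, for 12393 gene symbols. No symbol was changed by the mouse gene table used as a reference. No positions are given, because the genome build behind the array annotation is not named.

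Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group and variances moderated with a mean trend. Tests were two-sided, with Benjamini-Hochberg adjustment over the 22626 probe sets of each comparison and a threshold of 0.05. The comparisons were dexamethasone minus vehicle over all 4 lines (construct and genotype combinations), within each genotype and within each line, the difference of this response between genotypes and between constructs, and the differences between genotypes and between constructs in vehicle. The fit with no block, the gene lists and the rule for named genes were fixed before the data were examined, and the fit with the animal as a block is printed beside it because the values pair the arrays. P-values of single measures over 8 animals or fewer are from exact permutation tests, two-sided, which exchange the genotype labels or flip the signs of the animals' responses. Standard errors are written after the log2 difference, and standard deviations (SD) after signals.

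In all, 25 gene lists set at the same time were tested on 1 probe set per gene, the one with the highest mean log2 value, with camera of limma at its preset correlation of 0.01. P-values were adjusted over the lists of a comparison. Camera with a correlation estimated from the data was run beside it, and so was fry, which tests whether a list's genes move on balance one way and does not compare them with other genes. For each list the members called over all probe sets and those called when adjusted over the list alone were counted. The lists include markers of myeloid, erythroid and megakaryocytic, T and NK, and stromal cells, which bone marrow cultures can hold.

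Genes were named by a rule set in advance: for each comparison the 12 largest positive and 12 largest negative log2 differences among called probe sets with a single symbol and the same sign in each line or genotype averaged. Each gene was represented by its probe set with the highest mean log2 value, so that a gene called only by another probe set is not among them. The response within a single line had no named genes of its own. From each list up to 4 members with the largest absolute log2 difference were taken, and Gfi1b, Gfi1, Nr3c1, Bcl2l11, Fkbp5 and Tsc22d3 were always named. Genes named outside this rule are stated to be chosen after their values were seen.

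The size of an animal's whole response was measured over the 9206 probe sets with a mean log2 of at least 9, as the slope of its log2 changes on the mean change of the other 7 animals, in which each genotype counted equally.

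The fits were tested on simulated data with 200 of 22626 probe sets changed. For the response over all lines, 62.5% of 2-fold and 97.5% of 4-fold changes were recovered with no block, and 90.5% and 100% with the animal block. For a difference of responses between genotypes, 0% of 2-fold and 66.5% of 4-fold changes were recovered with no block, and 28% and 92.5% with the animal block. For the genotype difference in vehicle the recovered shares were 21.5% and 91%. False calls made up 0.51 to 0.794% of calls for the response over all lines with no block, and 2.69 to 7.41% with the animal block. They made up 6.52 and 8.54% for the genotype difference in vehicle at 2-fold and 4-fold, and for the difference of responses 0% with no block and 8.20 and 4.15% with the animal block, so that some of these shares exceeded the nominal 5%. Each share comes from a single simulated data set, so a share above 5% does not show that the false discovery rate exceeds 5%. A list shifted by 0.4 was called in 20 of 20 runs, and over these runs 1 list that had not been shifted was called. The simulated genes varied independently of each other. These runs therefore do not show how often an unshifted list of correlated genes is called.

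The alternatives were quantile normalization, offsets of 1 and 128 in place of 32, removal of the dimmer 50% of probe sets, variances without a trend, 1 probe set per gene, a 2-fold minimum, the replicate number as a block, the animal as a block, hybridization day as a block, the line as a random block, each line left out and each array left out. The animal together with the day as terms, the animal as a random block and each experiment alone were added after the data were seen. A day term leaves the response over all lines to be estimated from experiment 2 alone, because day and treatment coincide in experiment 1. With 1 array of a group left out, the remaining one was assumed to vary like those of the other groups. Control probe sets were left out because they measure no mouse transcript of interest, and no group or array was left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.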

Results

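Transcript levels were measured on 16 arrays of mouse pre-B cells transformed by BCR-Abl, in 8 groups of 2 arrays: 2 BCR-Abl constructs, 2 genotype labels, and vehicle or 12 hours of dexamethasone, a synthetic glucocorticoid. Each of 8 mice gave 1 vehicle and 1 dexamethasone array, so that every line (construct and genotype) was represented by 2 mice. Arrays of a group correlated across probe sets with r = 0.944 to 0.966. The median signal per array was 251 to 332.

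In vehicle, the signal of Gfi1b, the gene carried by the transgene, went against the genotype labels. Gfi1b encodes a zinc finger repressor of blood cell genes, and it has 1 probe set (1420399_at) on the array. In vehicle its signal was 172 ± 104 (SD, n = 4) in arrays labelled transgenic and 456 ± 106 (SD, n = 4) in wt arrays, 2.77-fold lower in the arrays labelled transgenic. The ranges were 25.5 to 266 and 399 to 614. The log2 difference was -1.47, with an exact permutation p of 0.0286, the smallest that 4 arrays against 4 allow, and an adjusted p of 0.962 in limma. It was -2.17 in experiment 1 and -0.77 in experiment 2, each with an exact p of 0.333 that 2 arrays against 2 cannot lower, and with any 1 of the 4 wt arrays left out the exact p was 0.0571. A probe set that lies outside the transgene's sequence would not measure its mRNA, so these values do not show how much transgene was expressed. Cells with the transgenic label are called tg-labelled cells throughout.

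**Figure D1:**
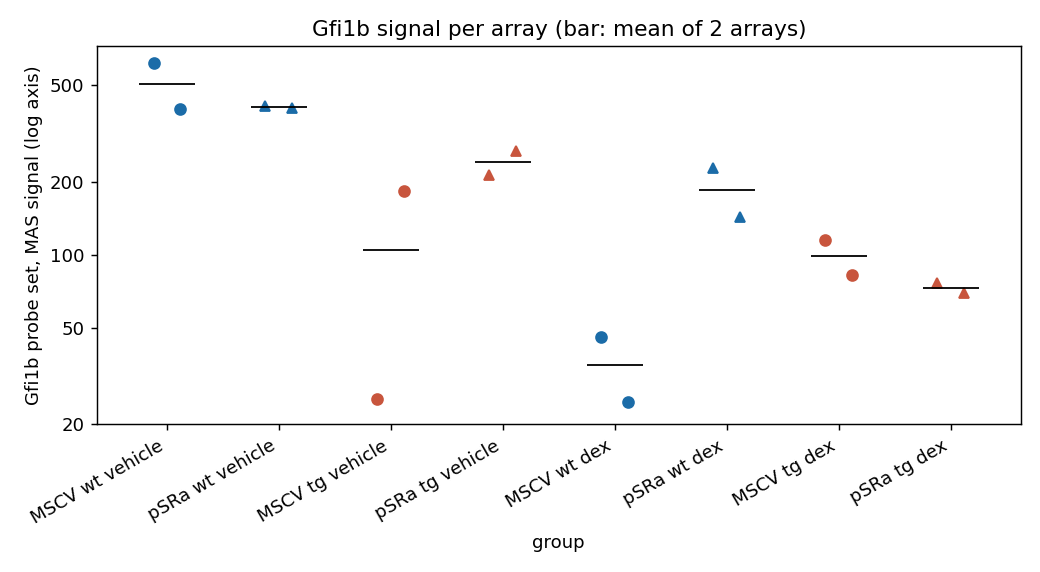
Signal of the Gfi1b probe set (MAS 5.0 intensity, log axis) in each of the 16 arrays by group, with wt in blue, tg-labelled in red, MSCV as circles, pSRa as triangles and a bar at the mean of 2 arrays. In vehicle the 4 wt arrays lie between 399 and 614 and the 4 tg-labelled arrays between 25.5 and 266.

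The first comparison asked which genes respond to dexamethasone in these cells. Known glucocorticoid-induced genes rose over the 4 lines (values are log2 differences ± standard error, 8 arrays per treatment). Fkbp5, a co-chaperone that restrains the glucocorticoid receptor, rose 3.73-fold (1416125_at, 1.90 ± 0.21, adjusted p = 0.00287), from a signal of 2584 ± 824 to 9621 ± 2292 (SD, n = 8). Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein, rose 3.37-fold (1.75 ± 0.20, adjusted p = 0.00413), from 1980 ± 729 to 6502 ± 1645 (SD, n = 8). The D-type cyclin gene Ccnd3 fell 2.60-fold (1415907_at, -1.38 ± 0.11, adjusted p = 0.000313), from 12957 ± 1390 to 5090 ± 1346 (SD, n = 8). Each of these 3 genes moved the same way in 8 of 8 animals.

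Among genes represented by their brightest probe set, the largest increases were in genes of varied function. Rpl3l, a ribosomal protein gene known from muscle, rose from a dim 23.5 ± 21.4 to 991 ± 1176 (SD, n = 8; 1449398_at, 3.59 ± 0.44, adjusted p = 0.005). Its size is set by the offset, because the vehicle level lies below 32, and was 5.03 with the smaller and 2.36 with the larger offset, so that no fold is given for Rpl3l. M1ap, a gene of male meiosis, rose 11.7-fold (1449358_at, 3.55 ± 0.20, adjusted p = 2.98e-05), from 195 ± 43.9 to 3622 ± 3008. Ptpn22, a phosphatase that restrains antigen receptor signalling, rose 9.11-fold (3.19 ± 0.38, adjusted p = 0.00452), and the pseudokinase gene Trib1 rose 5.55-fold (2.47 ± 0.38, adjusted p = 0.0198). The milk protein gene Csn2 rose 5.16-fold (2.37 ± 0.28, adjusted p = 0.00438), from 82.0 ± 48.5 to 1121 ± 1709. Slc25a53 rose 4.72-fold and Ppp1r21 3.91-fold, both with an adjusted p of 7.57e-05. Bbip1 rose 3.78-fold, the lymphangiogenic growth factor gene Vegfc 3.31-fold and the glycine cleavage gene Gldc 3.20-fold, with adjusted p of 0.00315, 0.00127 and 0.000605. Among the genes called by a probe set other than their brightest were Rpgrip1 (2.44, adjusted p = 0.0444), Rilpl1 (2.15, 0.0407) and Hip1r (1.81, 0.0198), named after their values were seen. Another probe set of Hip1r was also called, with a smaller 1.07 (adjusted p = 0.00557). Besides Ccnd3, the orphan nuclear receptor gene Esrrb fell 2.04-fold (-1.03 ± 0.19, adjusted p = 0.0497), and Inpp1, of inositol phosphate metabolism, fell 1.73-fold (-0.79 ± 0.11, adjusted p = 0.013). Apart from Rpgrip1, Rilpl1 and Hip1r, for which this was not counted, every gene named in this paragraph moved in its direction in 8 of 8 animals, and no other probe set of any of them went the opposite way.

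Among the genes named in advance, the receptor gene itself and the repressor genes gave weaker evidence. Nr3c1, the glucocorticoid receptor gene, had a signal of 2305 with dexamethasone against 1169 in vehicle and was higher in 8 of 8 animals (0.86 ± 0.23, adjusted p = 0.256), and it passed with the animal as a block (adjusted p = 0.0117) but not with animal and day together (0.125). The death gene Bcl2l11 had a log2 difference of 0.73 ± 0.24 (adjusted p = 0.378, and 0.103 with the animal block). Another of its 5 probe sets passed, with 0.82 and an adjusted p of 0.0444. Gfi1b had a signal of 98.0 ± 64.1 with dexamethasone against 314 ± 180 in vehicle (SD, n = 8) and was lower in 7 of 8 animals (-1.29 ± 0.26, adjusted p = 0.0786, 0.0197 with the animal block and 0.0742 with animal and day). The exact sign-flip p of Gfi1b was 0.0469. Gfi1, its close relative, had -0.16 (adjusted p = 0.922).

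**Figure D2:**
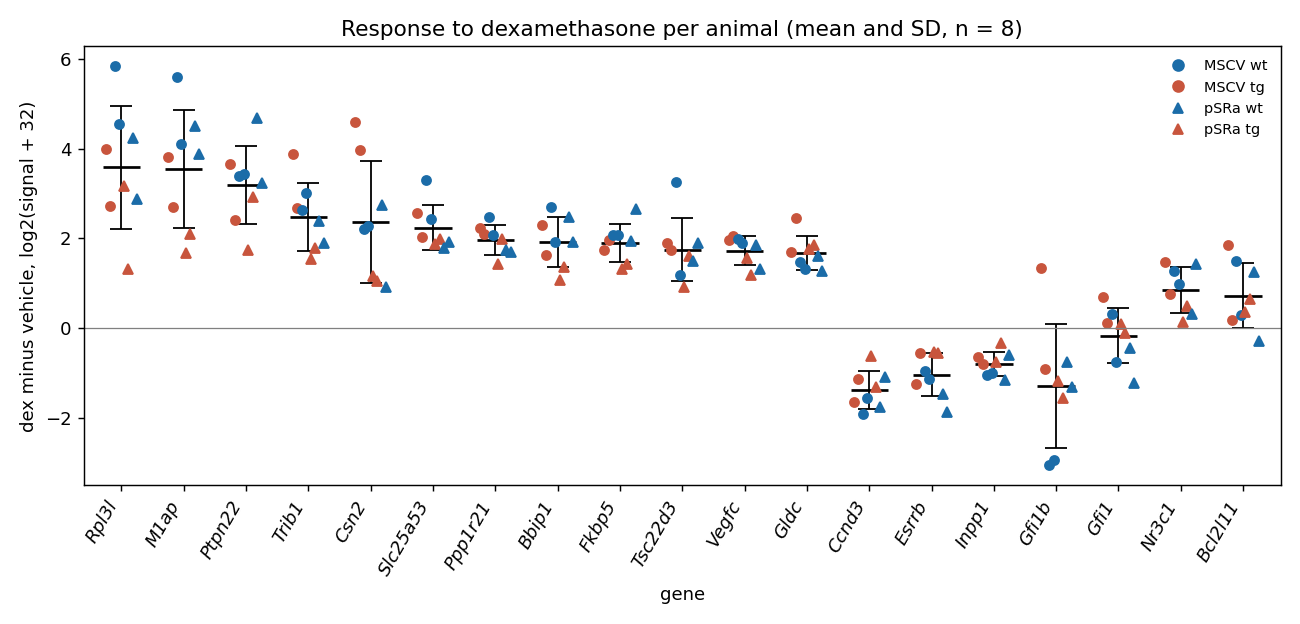
Change in log2 signal (dexamethasone minus vehicle) of 19 named genes in each of 8 animals, with wt in blue, tg-labelled in red, MSCV as circles, pSRa as triangles, and the mean and SD over the animals. M1ap averages 3.55 and Ccnd3 -1.38, and both lie on 1 side of 0 in 8 of 8 animals.

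Of 25 lists, 3 rose with dexamethasone: glucocorticoid receptor target genes, FOXO target genes and STAT5 target genes. These lists overlap, so their rises are not separate results. The FOXO list shares Irs2, Bcl6, Sesn1, Gadd45a and Il7r with the receptor target list, and the STAT5 list shares Bcl6 and Socs1 with it. Of 34 measured glucocorticoid receptor target genes, 25 lay above 0 and the median was 0.55 (camera adjusted p = 3.54e-11, and adjusted p = 0.0687 with an estimated correlation). In that list 6 members rose over all probe sets, among them Fkbp5, Tsc22d3, the thioredoxin-binding gene Txnip (1.45, adjusted p = 0.0053) and the mTOR inhibitor gene Ddit4 (1.28, adjusted p = 0.0124), the last 2 chosen after their values were seen. Adjusted over the list alone, 12 members were higher and 1 lower. The largest member by size, the MAP kinase phosphatase gene Dusp1, had 2.11 ± 0.49 (adjusted p = 0.157, 0.00665 with the animal block and 0.0950 with animal and day), and the cytokine receptor gene Il7r had 1.68 ± 0.64 (0.467, 0.00365 and 0.0822). FOXO target genes, which are induced when PI3 kinase signalling is low, had 15 of 22 members above 0 and a median of 0.16 (adjusted p = 0.000286, and adjusted p = 0.294 with an estimated correlation). The stress gene Sesn1 rose in that list (1.36, adjusted p = 0.00729), as did Cited2, chosen after its value was seen, with 5 higher and 0 lower when adjusted over the list alone. Irs2 had 1.36 (adjusted p = 0.0632) and Btg1 0.75. STAT5 target genes, a readout of the pathway that BCR-Abl drives, had 10 of 15 members above 0 and a median of 0.37 (adjusted p = 0.0181, and adjusted p = 0.673 with an estimated correlation). No STAT5 member passed over all probe sets in limma, 3 were higher when adjusted over the list alone, and the feedback inhibitor genes Cish and Socs1 had 0.80 and 0.81. Fry called 1 list of the 25, receptor targets (adjusted p = 0.0101).

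In all, 4 lists of growth and biosynthesis genes fell: DNA replication, cholesterol synthesis, amino acid stress (ATF4) genes, and MYC and ribosome biogenesis. Of 27 DNA replication genes 26 lay below 0, with a median of -0.50 (adjusted p = 3.27e-12, and adjusted p = 0.294 with an estimated correlation). Cdc6, which loads the replicative helicase, had -1.31 ± 0.37 (adjusted p = 0.295, 0.0146 with the animal block and 0.128 with animal and day), and Ccne2, Gins1 and Rfc3 had -0.78, -0.77 and -0.77. Mitosis genes had a median of -0.07 and did not pass (adjusted p = 0.427). Of 17 cholesterol synthesis genes 16 lay below 0, with a median of -0.58 (adjusted p = 1.97e-09, and adjusted p = 0.294 with an estimated correlation), with Cyp51 at -0.96, Hmgcs1 at -0.82 and Fdps at -0.79. Of 23 ATF4 genes 22 lay below 0, with a median of -0.46 (adjusted p = 3.53e-07, and adjusted p = 0.40 with an estimated correlation), with Atf3 at -1.16, the serine synthesis gene Psat1 at -0.99 and Mthfd2, of one-carbon metabolism, at -0.84. Of 25 MYC and ribosome biogenesis genes 20 lay below 0, with a median of -0.29 (adjusted p = 0.000302, and adjusted p = 0.294 with an estimated correlation), with the ribosome assembly genes Rrp9, Rrs1 and Nolc1 at -0.97, -0.75 and -0.74. Mxd4, an antagonist of MYC, had 1.46. No member of these 4 lists passed over all probe sets in limma. Adjusted over the list alone, 5 DNA replication genes, 10 cholesterol genes, 0 ATF4 genes and 5 MYC list genes were lower, and 2 MYC list genes were higher.

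**Figure D3:**
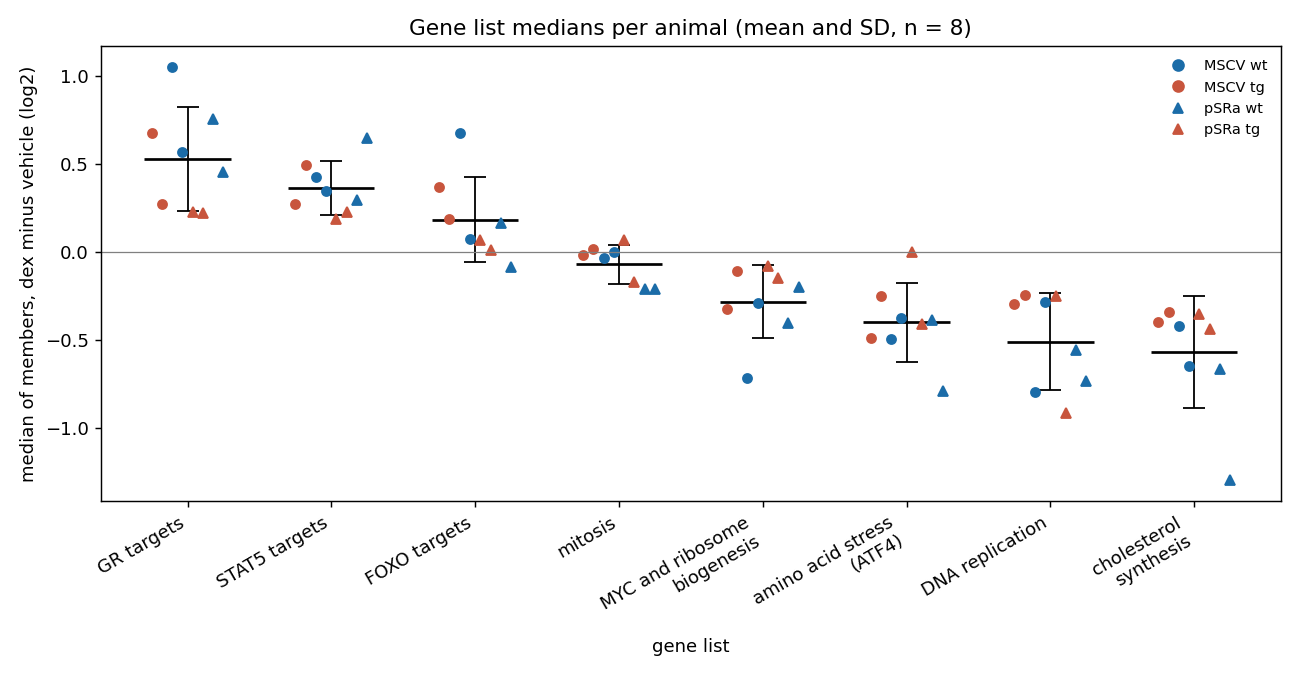
Median log2 change (dexamethasone minus vehicle) of the measured members of 8 gene lists in each of 8 animals, with wt in blue, tg-labelled in red, MSCV as circles and pSRa as triangles. DNA replication genes average -0.51 over the animals and mitosis genes -0.07.

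The other 18 lists did not pass. These were glycolysis, MAPK feedback genes, interferon response, pro-B and pre-B cell genes, and mature B cell genes (adjusted p = 0.342 each), MHC class II (0.221) and the GFI1 family with its reported targets (0.13). Receptor chaperones had 0.427, pro-apoptotic and anti-apoptotic BCL2 genes and B cell receptor signalling 0.742 each, and G1 cyclins and NF-kB genes 0.819 each. Among them 1 MHC class II member rose, H2-DMb2 (1.48, adjusted p = 0.0346), and Ccnd3 fell among the G1 cyclins. Markers of other cell types stayed within small medians: myeloid -0.07 (adjusted p = 0.298), erythroid and megakaryocytic -0.07 (0.427), and T and NK and stromal markers had an adjusted p of 0.742 each. In 5 lists, none of which passed, the median, the mean and the direction of the test differed in sign.

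In limma 71 probe sets passed over the 4 lines, 66 higher and 5 lower, and 2015 had an unadjusted p under 0.05, where chance gives 1131. All 71 had the same sign in each of the 4 lines. They cover 53 named genes, 49 higher and 4 lower, and 3 of the probe sets have no listed gene. The lower calls were Ccnd3, Esrrb, Inpp1, the deacetylase gene Hdac7 (-0.74, adjusted p = 0.0346, by a probe set other than its brightest and named after its value was seen) and 1 probe set with no listed gene. With the animal as a block 1284 passed, 641 higher and 643 lower, the 71 among them, and with animal and day together 89 passed, 75 higher and 14 lower. Of the 71, 41 passed with animal and day, and Tsc22d3 (adjusted p = 0.0774), Esrrb (0.103) and Inpp1 (0.0909) were among those that did not. That fit estimates the response over all lines from experiment 2 alone. The median absolute log2 change of the 71 was 1.16 there, against 1.36 in experiment 1. With the animal block 16 DNA replication genes, 10 cholesterol genes, 10 ATF4 genes and 9 MYC list genes were lower. Within experiments, tested alone with fewer arrays, 84 probe sets passed in experiment 1, where treatment and day coincide, and 64 in experiment 2, where all arrays shared a day. Of the 71, 32 and 39 passed in these experiments, and all 71 kept their direction in both. Their selection on arrays of both experiments favours this, so the kept direction is no independent support.

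List medians in experiment 1 and experiment 2 were 0.61 and 0.26 for receptor targets, 0.24 and 0.05 for FOXO targets, and 0.33 and 0.31 for STAT5 targets. They were -0.46 and -0.53 for DNA replication, -0.44 and -0.64 for cholesterol synthesis, -0.37 and -0.56 for ATF4 genes, and -0.44 and -0.22 for the MYC list. FOXO targets did not pass in experiment 2 alone (adjusted p = 0.101) or with animal and day together (0.145). With day as a block and no animal term, 3 of the 71 calls passed, and the FOXO, STAT5 and MYC lists did not (adjusted p = 0.0806, 0.0683 and 0.123). This fit, too, estimates the response over all lines from experiment 2 alone, so calls lost in it do not show an effect of the day. Glycolysis genes had a median of 0.10 in experiment 1 (adjusted p = 0.274) and -0.29 in experiment 2 (adjusted p = 0.000642), and over both experiments adjusted p = 0.837 with an estimated correlation. The count of 71 rested in part on single arrays and lines. It was 40 without the first MSCV wt vehicle array and 35 without its dexamethasone partner, 42 without the second MSCV wt vehicle array, 40 without the first MSCV tg-labelled dexamethasone array and 42 without the second MSCV tg-labelled vehicle array, and 41 and 47 without the second pSRa tg-labelled vehicle and dexamethasone arrays. Esrrb no longer passed whichever array was left out, H2-DMb2 in 12 of the 16 cases, Trib1 in 5, Inpp1 in 3, and the STAT5 list in 6. The STAT5 median was 0.20 without the second MSCV tg-labelled vehicle array (adjusted p = 0.213), and that of FOXO targets 0.099 without the first MSCV wt dexamethasone array. Without MSCV wt 14 probe sets passed, without MSCV tg-labelled 32, without pSRa wt 37 and without pSRa tg-labelled 39, and with 1 probe set per gene 41 passed.

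The next comparison asked whether the response differs with the vav-Gfi1b transgene. In wt cells M1ap rose 23.0-fold (4.52 ± 0.29, adjusted p = 9.37e-05), from 195 ± 39.3 to 5587 ± 3006 (SD, n = 4), and in tg-labelled cells 5.95-fold (2.57 ± 0.29, adjusted p = 0.0094), from 195 ± 54.3 to 1657 ± 1332 (SD, n = 4). Slc25a53 rose 5.14-fold in wt and 4.34-fold in tg-labelled cells, and Ppp1r21 4.01-fold and 3.81-fold. Ccnd3 fell 2.98-fold in wt (-1.58 ± 0.16, adjusted p = 0.00289) and 2.26-fold in tg-labelled cells (-1.18 ± 0.16, adjusted p = 0.0395). Each of these moved in its direction in 4 of 4 animals of either genotype. No gene differed in its response between the genotypes in limma.

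In wt cells Rpl3l also rose (4.37 ± 0.62, adjusted p = 0.0253, but 0.0516 with the larger offset), as did Ptpn22 (3.69), Bbip1 (2.25), Fkbp5 (2.19), the sialyltransferase gene St3gal1 (2.14), Polr3gl (1.98), Tsc22d3 (1.96), the lymphocyte survival GTPase gene Gimap3 (1.88) and Vegfc (1.76), with adjusted p of 0.00716 to 0.0442 and the same direction in 4 of 4 animals. In tg-labelled cells Gldc rose (1.94 ± 0.21, adjusted p = 0.0094, 4 of 4 animals). Fkbp5 had 1.61 there (adjusted p = 0.259), in 4 of 4 animals, and passed with the animal block (0.00188) and with animal and day (0.0132). The same probe set of Tsc22d3 had 1.55 (adjusted p = 0.259, 0.113 with the block and 0.474 with animal and day), and another probe set of Tsc22d3 passed with 1.73. Gfi1b had -2.01 in wt cells (adjusted p = 0.0872, and 0.0206 with the animal block) and -0.57 in tg-labelled cells (adjusted p = 1, and 0.637 with the block). Its difference of responses was 1.44 (adjusted p = 1, and 0.81 with the block), with an exact permutation p of 0.229.

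In limma 24 probe sets passed in wt cells, 23 higher and 1 lower, and 6 in tg-labelled cells, 5 higher and 1 lower, with 1830 and 672 at an unadjusted p under 0.05. All 6 were among the 24. The 24 wt calls had the same direction in tg-labelled cells, and 23 of them were larger in wt, with a median absolute log2 change of 1.97 against 1.47. Calls picked in 1 group tend to be larger there. The difference of responses itself gave 0 probe sets in limma, with 473 at an unadjusted p under 0.05, and 0 with the animal block, with 1363. Chance gives 1131, so the fit with no block was cautious here. Fkbp5, Tsc22d3 and Nr3c1 had differences of -0.58, -0.41 and -0.28 (adjusted p = 1 each), with exact permutation p of 0.0571, 0.571 and 0.486. Of the other probe sets of these genes, 1 of Nr3c1 (1421866_at) had -0.73 with an exact p of 0.0286, the smallest that 4 animals against 4 allow and not adjusted for the probe sets looked at, and 1 of Fkbp5 had -0.71 with 0.0571. With the animal block 820 passed in wt, 430 higher and 390 lower, and 55 in tg-labelled cells, 52 higher and 3 lower, and with animal and day 93 and 5. With animal and day, Tsc22d3 in wt cells (adjusted p = 0.0815) and M1ap and Ccnd3 in tg-labelled cells (0.0603 and 0.251) did not pass.

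Of the 25 lists, 0 differed in response between genotypes by camera, glycolysis coming nearest (adjusted p = 0.055) and receptor targets next (0.0567), and fry gave 0. With the animal block 7 lists differed, none with an estimated correlation (adjusted p = 0.699 each). In that fit receptor targets had a median difference, tg-labelled minus wt, of -0.18 (adjusted p = 0.00406) and MHC class II genes of -0.26 (0.0224). Glycolysis had 0.27 (0.00213), ATF4 genes 0.31 (0.00383), cholesterol synthesis 0.38 (0.0194), MYC list genes 0.21 (0.0173) and DNA replication 0.16 (0.0194). The medians in experiments 1 and 2 were -0.43 and -0.04 for receptor targets, 0.18 and 0.40 for glycolysis, 0.19 and 0.34 for ATF4 genes, and -0.0028 and 0.59 for cholesterol synthesis. They were 0.35 and 0.10 for the MYC list, 0.30 and 0.01 for DNA replication, and -0.39 and -0.15 for MHC class II, and none of the 7 lists passed in both experiments alone. With 1 array left out, without the animal block, 7 lists passed without the second pSRa wt vehicle array, 6 without the second MSCV wt or second pSRa tg-labelled dexamethasone array, and 5 without the first MSCV tg-labelled vehicle, first pSRa wt dexamethasone or first pSRa tg-labelled vehicle array. There were 2 without the first MSCV wt vehicle array, and 1 without the first MSCV wt or MSCV tg-labelled dexamethasone array, the second MSCV wt vehicle array or either second MSCV tg-labelled array. In 5 lists median, mean and test direction differed in sign.

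The wt count was 8 in each experiment alone and 1 with day as a block. It was 4 and 6 without the first MSCV wt vehicle and dexamethasone arrays, 5 without the second MSCV wt vehicle array, 13 without the first pSRa wt vehicle array, and 10 and 5 without the second pSRa wt vehicle and dexamethasone arrays. Without the first or the second pSRa tg-labelled vehicle array it was 12. The tg-labelled count was 0 in experiment 1, 3 in experiment 2, and 0 with day as a block. It was 3 and 1 without the first MSCV tg-labelled vehicle and dexamethasone arrays, 3 without the second MSCV tg-labelled vehicle array, 2 without the first pSRa tg-labelled vehicle array, and 1 and 0 without the second pSRa tg-labelled vehicle and dexamethasone arrays. Among the named wt calls, Gimap3 no longer passed in 11 of the 16 cases, Rpl3l, Polr3gl and Tsc22d3 in 9 each, Ptpn22 in 7, Fkbp5 and Vegfc in 6 each, Bbip1 in 4 and St3gal1 in 3. Among the tg-labelled calls, Ccnd3 no longer passed in 14 cases, M1ap in 6, Gldc in 4, Slc25a53 in 3 and Ppp1r21 in 1.

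Within single lines, with 2 animals each, few genes passed. M1ap rose in MSCV wt cells (4.85), in MSCV tg-labelled cells (3.26) and in pSRa wt cells (4.19). In MSCV wt cells Slc25a53 (2.87) and Ppp1r21 (2.28) rose too and Ccnd3 fell (-1.73), which made 4 calls. In MSCV tg-labelled cells both probe sets of Csn2 rose (4.28 and 3.18), with Slc25a53 (2.30) and Ppp1r21 (2.16), which made 5 calls. M1ap was the 1 call in pSRa wt cells, and limma gave 0 in pSRa tg-labelled cells. These genes were named after their values were seen. At an unadjusted p under 0.05 the 4 lines had 1191, 593, 1065 and 383 probe sets, and with the animal block 83, 27, 52 and 2 passed. The MSCV wt count was 0 without the first MSCV wt vehicle array, 1 without its dexamethasone partner or the second MSCV wt vehicle array, and 2 without either pSRa wt vehicle array. The MSCV tg-labelled count was 0 to 2 whichever array was left out. The pSRa wt count was 0 without either pSRa wt vehicle array or the second dexamethasone array, and 9 without the first dexamethasone array.

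A further comparison asked whether the response differs with the BCR-Abl construct. The MYC and ribosome biogenesis list, which fell with dexamethasone over all lines, fell less in pSRa than in MSCV cells, by a median of 0.22 (camera adjusted p = 0.0424, and adjusted p = 0.874 with an estimated correlation). FOXO target genes, which rose over all lines, had a lower response in pSRa cells, by a median of -0.28 (adjusted p = 0.038, and adjusted p = 0.874 with an estimated correlation). The other 23 lists did not pass, and no single gene differed in limma.

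Limma gave 0 probe sets for this difference, with 389 at an unadjusted p under 0.05, and 0 with the animal block, with 1048. Fry gave 0 lists. With the animal block 6 lists differed, including MYC (0.00729), FOXO (0.0016), DNA replication (-0.22, 0.0016), receptor targets (-0.34, 0.0191), mitosis (-0.14, 0.0191) and pro-B and pre-B cell genes (-0.12, 0.0459), none with an estimated correlation (adjusted p = 0.574 or more). The median of the MYC list was 0.43 in experiment 1 and 0.01 in experiment 2, that of FOXO targets -0.45 and -0.08, and that of DNA replication 0.14 and -0.55. In experiment 2 alone neither the MYC list nor FOXO targets passed (adjusted p = 0.628 and 0.828). With quantile normalization the MYC list did not pass (adjusted p = 0.148). With 1 array left out the MYC list no longer passed in 10 of the 16 cases and FOXO targets in 7. The MYC median was 0.0081 without the first MSCV wt dexamethasone array, 0.089 and 0.10 without the second pSRa wt and pSRa tg-labelled vehicle arrays, and 0.14 without the first pSRa tg-labelled dexamethasone array. The FOXO median was -0.43 without the first MSCV tg-labelled dexamethasone array, -0.46 without the first pSRa wt vehicle array, -0.50 without the second MSCV tg-labelled vehicle array and -0.45 without the second pSRa tg-labelled dexamethasone array. No list passed without the first MSCV wt vehicle, first MSCV tg-labelled vehicle or dexamethasone, or second pSRa tg-labelled vehicle array, and 1 passed without the second pSRa wt vehicle array. Without the first pSRa wt, second MSCV wt or second MSCV tg-labelled dexamethasone array 4 lists passed.

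The genotype labels were then compared in vehicle, to ask what the transgene does without hormone, with the reservation that Gfi1b itself went against the label. Of 25 lists 2 differed, amino acid stress (ATF4) genes and myeloid cell markers, and neither kept its direction in both experiments. ATF4 genes were lower in tg-labelled cells, with 19 of 23 below 0 and a median of -0.23 (camera adjusted p = 0.0306, and adjusted p = 0.909 with an estimated correlation). Its largest members were the glutathione-degrading gene Chac1 at -0.80, asparagine synthetase Asns at -0.52, Atf3 at -0.52 and Mthfd2 at -0.43. Myeloid markers were higher, with 17 above 0 and 7 below and a median of 0.12 (adjusted p = 0.0306, and adjusted p = 0.909 with an estimated correlation). The lysozyme gene Lyz1 had 1.09 (adjusted p = 0.874), Tyrobp 0.99, Prtn3 0.72 and Cybb 0.64, and 1 member was higher when adjusted over the list alone. Erythroid and megakaryocytic markers had a median of 0.02 (adjusted p = 0.859).

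In limma 0 probe sets differed between the genotype labels in vehicle over both constructs, with 595 at an unadjusted p under 0.05 and a smallest adjusted p of 0.164. That adjusted p belonged to genes chosen after their values were seen. Among them were Gldc (-1.46 ± 0.21, 2603 ± 845 in tg-labelled against 7039 ± 1109 in wt arrays, SD, n = 4), the lymphocyte gene Arpp21 (-2.31 ± 0.34) and the lysosomal thiol reductase gene Ifi30 (2.07 ± 0.31). With the replicate number as a block 0 passed, with 804 at an unadjusted p under 0.05. Within MSCV cells 1 probe set passed, 1450943_at, which has no listed gene: its signal was 7.45 in tg-labelled and 2162 in wt vehicle arrays (-5.80 ± 0.62, adjusted p = 0.0252). The lower signal lies below the offset of 32, which sets the size of the difference, and with the larger offset 0 probe sets passed. It was 8.6 and 1258 in the dexamethasone arrays of the same lines, and 1669 and 1319 in tg-labelled and wt vehicle arrays of pSRa cells. Within pSRa cells limma gave 0, with 605 at an unadjusted p under 0.05. The median of ATF4 genes was 0.07 in experiment 1 and -0.48 in experiment 2, and that of myeloid markers 0.33 and -0.04. Fry gave 0 lists, and without either of the MSCV lines 0 lists passed. ATF4 genes did not pass without the first pSRa wt, second MSCV wt, second MSCV tg-labelled or second pSRa tg-labelled vehicle array, and myeloid markers did not without the first vehicle array of any of the 4 lines or the second pSRa tg-labelled one. The ATF4 median was -0.15 without the second MSCV wt or MSCV tg-labelled vehicle array, -0.11 without the second pSRa tg-labelled one and -0.36 without the first pSRa tg-labelled one. The myeloid median was 2.33e-05 without the first pSRa wt vehicle array, 0.035 without the first MSCV tg-labelled one and 0.072 without the first MSCV wt one, and it was 0.23 and 0.19 without the second MSCV tg-labelled and pSRa wt ones. Without the first MSCV tg-labelled vehicle array 4 lists and 1 probe set passed. The probe set 1450943_at did not pass without any 1 of the 8 MSCV arrays.

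The last comparison set the BCR-Abl constructs side by side in vehicle, where the construct cannot be told from other features of the lines. Of 25 lists 8 differed, 3 lower and 5 higher in cells with pSRa. The MYC and ribosome biogenesis list was lower in pSRa cells, with 21 of 25 genes below 0 and a median of -0.42 (camera adjusted p = 9.82e-08, and adjusted p = 0.189 with an estimated correlation), Rrp9 being at -0.97, the MYC relative Mycn at -0.89 and Nop58 at -0.80. FOXO target genes were higher, with 21 of 22 above 0 and a median of 0.57 (adjusted p = 4.08e-05, and adjusted p = 0.249 with an estimated correlation), with Gadd45a at 1.31, S1pr1 at 1.05, Btg1 at 0.97 and Sesn3 at 0.95. The MYC and FOXO differences share their vehicle arrays with the opposite differences in response given above, so they are not separate results. DNA replication (-0.28, adjusted p = 6.5e-05) and mitosis genes (-0.16, 0.00331) were lower (adjusted p = 0.472 and 0.249 with an estimated correlation).

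MAPK feedback and immediate early genes were higher in pSRa cells, by a median of 0.43 (adjusted p = 0.00441, and adjusted p = 0.249 with an estimated correlation), with Etv4 at 1.24, Jun at 1.05, Egr3 at 0.86 and Dusp6 at 0.72. Pro-B and pre-B cell genes were higher, by 0.33 (adjusted p = 0.0313, and adjusted p = 0.532 with an estimated correlation). The recombination genes Dntt and Rag1 were at 2.0 and 1.28, the kinase gene Blk at 1.37 and the B lineage regulator Pax5 at 0.68. Cholesterol synthesis was higher by 0.32 (adjusted p = 0.0474, and adjusted p = 0.532 with an estimated correlation). Erythroid and megakaryocytic markers were higher by 0.23 (adjusted p = 0.0198, and adjusted p = 0.249 with an estimated correlation), with Car1 at 1.08, Hba-a1 at 0.99 and Slc4a1 at 0.95. Car1 was dim, with a mean vehicle signal of 58.6. The median over all probe sets was 0.083 in this comparison, and -0.0016 with quantile normalization, so part of each list's median is a shift of all probe sets. Myeloid markers did not pass, with a median of 0.06 that was -0.07 with quantile normalization (adjusted p = 0.365), and 2 of them, Lyz1 (-1.17) and Mcpt8 (-1.04), were lower when adjusted over the list alone.

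No single gene passed between the constructs over both genotypes in limma, with 1817 probe sets at an unadjusted p under 0.05. The nearest, chosen after its value was seen, was the glucosyltransferase gene Poglut2 (-1.71 ± 0.20, 1030 ± 808 in pSRa against 2673 ± 517 in MSCV arrays, SD, n = 4, adjusted p = 0.0521). With the replicate number as a block 3 probe sets passed, 2 of the mannosidase gene Man1a (1.04 and 0.99), named after their values were seen, and 1 of Poglut2. With quantile normalization the mitosis list (adjusted p = 0.0611) and the erythroid and megakaryocytic list (0.0603, with a median of 0.081) did not pass. Fry called 5 lists, 3 of them among these 8. List medians in experiments 1 and 2 were -0.23 and -0.50 for MYC, 0.65 and 0.51 for FOXO, -0.05 and -0.48 for DNA replication, -0.09 and -0.18 for mitosis, and 0.22 and 0.52 for MAPK genes. They were 0.35 and 0.30 for pro-B and pre-B cell genes, 0.41 and 0.17 for cholesterol synthesis, and 0.29 and 0.30 for erythroid and megakaryocytic markers. DNA replication and MAPK genes did not pass in experiment 1 alone (adjusted p = 0.0839 and 0.0768), nor did cholesterol synthesis and erythroid and megakaryocytic markers in experiment 2 alone (0.645 and 0.057). With 1 array left out, cholesterol synthesis no longer passed in 9 of the 16 cases. Its median was 0.063 without the first MSCV wt vehicle array (adjusted p = 0.972), 0.21 without the first MSCV tg-labelled one, 0.18 without the second pSRa wt one and 0.54 without the second MSCV wt one. Pro-B and pre-B cell genes did not pass without the first MSCV tg-labelled, first pSRa wt, second MSCV wt or second pSRa tg-labelled vehicle array, and erythroid and megakaryocytic markers without the first MSCV tg-labelled, first pSRa tg-labelled or second MSCV wt vehicle array. Mitosis genes did not pass without the first pSRa tg-labelled vehicle array, MAPK genes without the second MSCV tg-labelled vehicle array, and DNA replication without the second pSRa wt vehicle array. The pro-B and pre-B cell median was 0.17 without the first MSCV tg-labelled vehicle array, 0.20 without the second pSRa tg-labelled one and 0.51 without the first. The erythroid and megakaryocytic median was 0.38 without the first MSCV wt vehicle array, and the DNA replication median -0.096 without the second pSRa wt one. The mitosis median was -0.093 and -0.088 without the first pSRa tg-labelled and second pSRa wt vehicle arrays, and -0.25 without the first MSCV tg-labelled or the second pSRa tg-labelled one. In limma 1 probe set passed without either of the MSCV wt dexamethasone arrays.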

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

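Of the tests in this part, the counts over other splits of the arrays and the test of Gfi1b against equally dim probe sets were set before their results were seen, and those on the size of the response, the hybridization day, exchanged labels and Gfi1 were chosen afterwards.

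For dexamethasone over all lines, chance is unlikely. With line means kept, but not the pairing by animal, 2 of 100 splits of the 16 arrays gave as many probe sets as the real split. The real one gave 120 and the highest of the others 307. That other split parted 0 of the animals' pairs, so it set animals against each other. Its count points to differences between animals or between the experiments they belong to. When vehicle and dexamethasone were exchanged within some of the animals, which parts as many pairs as the real split, 1 of 100 gave as many, the real 71, and the highest other gave 5. For wt cells alone, counted with line means kept as well, chance cannot be excluded, since 2 of 35 splits gave as many, with 31 in the real split and 114 in the highest other. That split parted 0 pairs and set the arrays of experiment 1 against those of experiment 2, while further splits that parted 0 pairs gave 10 and 0. The other 7 splits that parted all 4 pairs gave 0. For tg-labelled cells chance cannot be excluded either, since 3 of 35 splits gave as many, with 8 in the real split and 247 in the highest other. That split, too, parted 0 pairs and set experiment 1 against experiment 2, while further splits that parted 0 pairs gave 2 and 56. The other 7 splits that parted all 4 pairs gave 0. The 8 splits that part all 4 pairs are too few for a share under 0.05 in either genotype. For genotype and construct in vehicle, and for the differences of responses between genotypes and between constructs, the real count was 0, so that all 35 of 35 splits gave as many by construction and the counts say nothing about chance. The highest of the other splits gave 2 in vehicle and 1 for the responses.

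The responses of tg-labelled cells were smaller on average: the response slope was 0.68 ± 0.266 against 1.03 ± 0.354 in wt cells (SD, n = 4 animals), and wt was above tg-labelled in 4 of 4 pairs of the same construct and experiment. Hybridization day as the whole cause is argued against by the design, since both genotypes shared the same days in each experiment. In experiment 2, run on a single day, the difference was 0.25 against a pooled SD of 0.115. That value rests on 2 animals per genotype, and its slopes were taken on a mean that includes animals of experiment 1. Chance among 8 animals remains open (exact permutation p = 0.171, with labels exchanged regardless of construct and experiment). The 4 pairs alone are too few for a two-sided exact p under 0.05. Whether a single animal sets the size is open as well. Without the first MSCV wt animal the difference was 0.175, the lowest with any 1 animal left out and within the pooled SD of 0.313. A lower receptor level in tg-labelled cells stays open too, as Nr3c1 in vehicle gave an exact p of 0.371, which does not show equal levels. An effect of the transgene on the response, the biological explanation the design names, may hold but is untested here. The contrary Gfi1b signal in vehicle leaves the label itself unsettled.

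In experiment 1 the dexamethasone arrays were hybridized on another day than the vehicle arrays, so that the day could account for some of the changes. Of the 84 probe sets called in experiment 1 alone, 95.2% had the same sign in experiment 2, where all arrays shared a day, and the highest of 100 random sets of that size reached 70.2%. This argues against the day as the cause of those calls as a whole. The 4 lists that fell had a mean median of -0.49 in experiment 2. In its 4 animals the medians were -0.92 to -0.24 for DNA replication and -1.30 to -0.34 for cholesterol synthesis. They were -0.79 to -0.25 for ATF4 genes and -0.29 to -0.11 for the MYC list. These values argue against the day as the whole cause of the falls. They are no independent evidence of a fall, because the lists were chosen on arrays that include those of experiment 2. Random sets of genes, with a lowest value of -0.17, lack the correlation within a list. A contribution of the day to the size of single genes in experiment 1 cannot be separated from the treatment.

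The Gfi1b probe set was lower in tg-labelled arrays in vehicle, by a log2 difference of -1.47, although the label says that these cells carry more of the gene. Noise of a dim probe set is argued against, since 0.7% of the 1000 probe sets nearest in mean level differed as much. Exchanged genotype labels cannot be told apart from true ones by the difference of -1.47 itself, because an exchange would turn every genotype difference and the arrays hold no other readout of the transgene. Another candidate explanation is that the transgene's product lowers the cell's own Gfi1b while the probe set misses the transgene mRNA. For that, Gfi1, a reported target of the same repressor family, gave 25.9 ± 33.5 in tg-labelled and 87.0 ± 58.4 in wt arrays (SD, n = 4) with an exact p of 0.0857, which does not decide, and how far any of these accounts for the signal stays open.

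Single animals or arrays stood far from the others of their group in 4 of 39 groups tested, where chance gives about 1 in 20. Tsc22d3 responded by 3.26 in the first MSCV wt animal, with the next animal at 1.90. The median of cholesterol synthesis genes was -1.30 in the second pSRa wt animal, with the next at -0.67. Gfi1b in vehicle was 614.5 in the first MSCV wt array, with the next wt array at 408. Gfi1 in vehicle was 76 in the second MSCV tg-labelled array, with the next at 12.9. Between constructs, the response of the MYC and ribosome biogenesis list differed by 0.22 and that of FOXO targets by -0.28 in a test of the difference at the preset correlation, which neither passed with an estimated correlation (adjusted p = 0.874 each), and in experiment 2 alone the values were 0.015 and -0.084.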

How the results depend on the processing

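The alternatives with animal and day together, the animal as a random block, each experiment alone, and those of the gene lists and Gfi1b other than the ones set at the start were chosen after the data were seen. All 71 calls over the 4 lines kept their direction under every alternative that tested them, with the count at 61 to 103 under scaling, offset, trend and replicate block, and both interactions and the pSRa genotype difference stayed at 0 probe sets. The kept direction is no independent support, because the 71 were selected on the same arrays. Where a result changed, the cause was not tested, except that leaving out lines, arrays or an experiment leaves fewer samples and 1 probe set per gene leaves fewer tests. A day term likewise leaves the response over all lines to the arrays of experiment 2. Signal over background limits dim genes such as Gfi1b and Gfi1. These 2 have 1 probe set each, so no other could be tried, and the line as a random block was run only for averaged differences.

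With the animal block the counts were 1284 over all lines, 820 in wt, 55 in tg-labelled, 83 in MSCV wt, 27 in MSCV tg-labelled, 52 in pSRa wt and 2 in pSRa tg-labelled cells, and 7 and 6 lists for the interactions with genotype and construct. With animal and day they were 93 in wt, 14 in MSCV wt and 8 in pSRa wt, and 7 and 6 lists. With day they were 3 over all lines, 1 in wt, 0 in tg-labelled, 1 in MSCV wt, 0 in MSCV tg-labelled and 0 in pSRa wt cells, and 1 list by genotype. With the replicate block they were 37 in wt, 3 for construct, 2 lists by genotype for the response and 4 for genotype in vehicle. In experiment 1 they were 8 in wt, 0 in tg-labelled and 1 for genotype, and 5, 4 and 5 lists for the interactions with genotype and construct and for genotype. In experiment 2 they were 8 in wt, 3 in tg-labelled and 1 for construct, and 3, 6 and 14 lists for the interaction with genotype, genotype and construct. Lines left out gave, for MSCV wt, MSCV tg-labelled, pSRa wt and pSRa tg-labelled, 14, 32, 37 and 39 probe sets over the other lines and 3, 3, 4 and 4 lists for the interaction with genotype. Lists were 1 for the interaction with construct without MSCV wt, MSCV tg-labelled or pSRa wt, 0, 0 and 1 for genotype without the same lines, and 5 and 4 for construct without MSCV wt and pSRa wt.

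With 1 probe set per gene 41 passed over all lines, 0 for genotype in MSCV and 1 for construct. Without the dimmer probe sets 8 passed in MSCV wt, 3 in MSCV tg-labelled and 1 for construct, and 8, 4 and 1 lists for the interactions and genotype. Without a trend 2 passed in MSCV wt and 0 in MSCV tg-labelled cells. Quantile normalization gave 0 for genotype in MSCV, 1 for construct and 1 list by genotype for the response. An offset of 1 gave 0 in MSCV tg-labelled, 1 for construct and 2 such lists, and the larger offset gave 0 for genotype in MSCV. The line as a random block gave 2 for genotype, and the animal as a random block 1 for construct. With an estimated correlation 0 lists passed in any comparison, with or without the animal block, and fry gave 1 for dexamethasone, 0 for the interaction with construct, 0 for genotype and 5 for construct.

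With 1 array left out the counts were 35 to 90 over all lines, 4 to 35 in wt, 0 to 6 in tg-labelled, 0 to 5 in MSCV wt, 0 to 2 in MSCV tg-labelled and 0 to 9 in pSRa wt cells, and 0 to 1 for genotype, genotype in MSCV and construct. Lists were 6 to 8 for dexamethasone, 0 to 7 and 0 to 4 for the interactions, 1 to 4 for genotype and 6 to 9 for construct. Gfi1b in vehicle ran from -1.73 to -0.94, and was -2.17 in experiment 1 and -0.77 in experiment 2. Reversed values were Gfi1 with dexamethasone at 0.17 in experiment 1, 0.059 without pSRa wt and -0.36 to 0.028 with 1 array left out (above 0 without the second MSCV wt dexamethasone array), Nr3c1 by genotype at 0.0011 in experiment 2, ATF4 genes by genotype at 0.069 in experiment 1, and myeloid markers by genotype at -0.041 in experiment 2 and -0.050 without MSCV wt or MSCV tg-labelled cells. Over all results and alternatives, those printed included, 3231 values under an alternative kept their direction and side of the test or, for counts, stayed close, 165 counts moved further, 80 values came to pass, 369 no longer passed and 8 were reversed.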

Other observations

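Id3, Lifr, Hvcn1, Il33 and Samhd1 were chosen after their values were seen, and so was the test of DNA replication against mitosis genes. The other genes are members of the lists named by the rule set in advance. With the animal as a block, single genes moved with dexamethasone over the 4 lines (log2 differences, 8 arrays per treatment, adjusted p of that limma fit). The recombinase gene Rag1 fell (-1.89, adjusted p = 0.00259, 8 of 8 animals), as did Sox4 (-0.75, 0.0321), while Il7r rose (1.68, 0.00365, 8 of 8). The pro-B and pre-B cell list, which holds Rag1, Sox4 and Il7r, had 1 member higher and 4 lower. Its median was -0.23 and it passed in that fit (adjusted p = 0.034, and adjusted p = 0.40 with an estimated correlation), where without the block it did not (0.342). The helix-loop-helix inhibitor genes moved apart, Id2 rising (1.63, adjusted p = 0.00491) and Id3 falling (-1.69, 0.0186), each in 8 of 8 animals. Jchain (-0.82, 0.0015) and Sdc1 (-1.08, 0.04) fell, while Spib rose (0.64, 0.00995), and their list, mature B cell and plasma cell genes, did not pass (0.24).

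Members of the BCL2 lists went both ways in the same fit, and neither list passed (adjusted p = 0.975 for the pro-apoptotic and 0.715 for the anti-apoptotic list). The survival gene Bcl2 rose (0.66, adjusted p = 0.00413, 8 of 8 animals) and Bcl2l1 fell (-0.49, 0.0143, 8 of 8), while the death gene Bmf rose (0.71, 0.0433, 7 of 8) and Bok fell (-0.99, 0.0468, 7 of 8). The death gene Bcl2l11 did not pass by its brightest probe set (0.73, 0.103), but another of its probe sets rose and passed (0.82, 0.0176). Inpp5d (0.60, 0.00682) and Ptpn6 (0.53, 0.0185) rose. In the B cell receptor signalling list that holds them 2 other members were lower, and the list did not pass (0.891). Spry1 rose (0.71, 0.00631) where the MAPK feedback list did not pass (0.24). The lactate transporter gene Slc16a1 fell (-0.72, 0.0139). The leukaemia inhibitory factor receptor gene Lifr (2.83, 0.00215), Hvcn1 (1.77, 0.0105), the cytokine gene Il33 (1.75, 0.000175) and Samhd1 (1.73, 0.00372) rose in 8 of 8 animals each. Of the genes in these paragraphs only Id2 and Bcl2l11 passed without the block, each by a probe set other than its brightest (adjusted p = 0.0327 and 0.0444). With the day added to the animal block, which took the calls from 1284 to 89, Rag1 (0.00783), Id2 (0.0339), Jchain (0.0415), Lifr (0.0473) and Il33 (0.00783) passed. The other genes named here did not (0.0771 to 0.358, and 0.707 for Bcl2l11 by its brightest probe set).

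A hypothesis drawn from these data is that dexamethasone lowers DNA replication genes more than mitosis genes within each animal. The median change of replication genes was below that of mitosis genes in 8 of 8 animals, by -0.76 to -0.26. The medians averaged -0.51 ± 0.28 and -0.07 ± 0.11 (SD, n = 8), and their difference -0.44 ± 0.21 had an exact two-sided sign-flip p of 0.00781, the smallest that 8 animals allow. Because the hypothesis came from the medians of these same animals, this p describes how regular the difference was and is no independent evidence for it. The difference was -0.43 in experiment 1 and -0.45 in experiment 2, and cell cycle phases were not measured.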
